A study of Mus musculus with 6 samples.

How the data were processed

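Expression was profiled by high-throughput sequencing of RNA, per the labels. Total RNA was extracted with Trizol and made into Illumina libraries, per the labels' protocols. The submitters' processing notes name cutadapt version 1.9, FastQC and the mouse build GRCm38. The aligner and the counting tool are not given in the sources used here. The single deposited table was a table of human genes, with FPKM and counts per gene, per the file headers. Why the organism of its annotation differed from the labels was not established.

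The design was fixed before the data were examined. It called for a gene-by-gene test of LPS with hydroprotopine against LPS alone, tests of fixed gene lists, and a set of alternative settings. None of these was run, and the rule for naming genes by their test results was not applied. The 14 genes whose positions were compared are the ones that the rule named whatever their values. The 12 columns of per-sample values, 6 of FPKM and 6 of counts, were left out of every result. The 6 DMSO columns matched no label by name. The 6 HPT columns shared that abbreviation with 3 sample titles, but the human genes of the table did not match the organism of those samples. The values had been inspected once, only to learn what the table holds. The genes viewed included PTPRC, SPI1 and CSF1R, genes of leukocytes and macrophages, and CD68, also used as a macrophage marker. They also included the fibroblast-associated genes THY1, COL1A2 and MMP1. No list of genes and no detection threshold had been set for that look, so no level is given. The cells behind the columns were not identified. That look was not turned into a measurement, and no result rests on it. Depth per sample is not reported for the same reason.

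What was computed came from the annotation columns alone, with Python 3.11.15 and pandas 2.3.3. Rows were counted by the prefix of their gene and transcript identifiers and by the database cited in their description. Gene identifiers were compared, without version numbers, with those of GENCODE M21. A row was counted outside the span of annotated mouse genes where its chromosome name did not occur in that annotation. A row was also counted where its end lay beyond the last mouse gene of that chromosome, which is not the chromosome's end. Coordinates were not converted between builds, and the positions of the table and of the mouse annotation were only set side by side. These are counts over all rows of one table, so they have no replicate error.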

Results

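The series was set up to compare RAW264.7 cells, an established mouse macrophage line, given lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages, with the same cells given LPS together with hydroprotopine. The labels describe 6 mouse samples in 2 groups, 3 with LPS alone and 3 with LPS and hydroprotopine. No comparison between these groups was made, because the table read here describes human genes and its columns could not be assigned to the labelled samples.

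All 29640 rows of the table carried a human Ensembl gene identifier, and all 29640 listed human transcript identifiers. No row therefore had a mouse Ensembl gene identifier (0 rows). For the same reason, 0 of the gene identifiers occurred in the mouse annotation, GENCODE release M21 on GRCm38. The gene descriptions of 22100 rows cited the human nomenclature committee, HGNC, and 0 cited the mouse database, MGI. Of the rows, 16041 included a protein-coding transcript and 6729 listed only long non-coding RNA.

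The positions in the table were likewise not those of the mouse genome. Chromosomes 20, 21 and 22, which the mouse lacks, held 726, 428 and 711 rows. On chromosome 1 the last gene of the table ended at position 248937043, whereas the last gene of the mouse annotation ended at 195323493. The order was reversed on chromosomes 13 to 19, for example 114346637 in the table against 120318178 in the mouse on chromosome 13. On those chromosomes no row could end beyond the last annotated mouse gene. In all, 4972 rows, 16.8% of the table, lay on a chromosome that the mouse lacks or ended beyond the last annotated mouse gene of the chromosome with that name.

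The 14 genes that the design named in advance were placed differently in the table and in the mouse annotation. Matched by symbol without regard to case, 3 of the 14 lay on a chromosome of the same number in both. Every row carried a human identifier, so positions other than those of the mouse followed for any genes, not for these in particular. The LPS receptor gene TLR4 (ENSG00000136869) was given on chromosome 9 from 117704175 to 117715775 on the plus strand, while mouse Tlr4 lies on chromosome 4 from 66827584 to 66930284. The inflammatory cytokine gene TNF (ENSG00000232810) was given on chromosome 6 from 31575565 to 31578336, while mouse Tnf lies on chromosome 17 from 35199381 to 35202007. NOS2 (ENSG00000007171), which encodes inducible nitric oxide synthase, was given on chromosome 17 from 27756766 to 27800529, while mouse Nos2 lies on chromosome 11 from 78920787 to 78960254. HMOX1 (ENSG00000100292), which encodes the haem-degrading enzyme haem oxygenase, was given on chromosome 22 from 35380361 to 35390293, while mouse Hmox1 lies on chromosome 8 from 75093621 to 75100589. The genome build of the table's coordinates is not given in the sources used here, and the mouse positions are those of GRCm38.

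The names of the value columns also differed from the labels. By their headers, 6 columns held FPKM and 6 held counts. For each measure, 3 columns were named DMSO and 3 were named HPT. The word DMSO occurred in the labels of 0 of the 6 samples, so the DMSO columns matched no sample. The abbreviation HPT occurred in 3 sample titles, all of the group given LPS and hydroprotopine, but these samples are labelled as mouse cells. The expression values were therefore assigned to no sample, and no level, fold change or test of hydroprotopine treatment is given.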

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

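The measures of the organism of the table's annotation and their alternatives were all chosen after seeing the data. They used no expression values and did not test which species' RNA was sequenced. Human annotation covered 100% of rows by gene ID and 100% by transcript ID. It covered 74.56% by the source of the description, since that criterion leaves out rows whose description does not cite HGNC. The share of rows outside the span of annotated mouse genes was 16.77%, and 6.292% when only absent chromosomes counted. Names spelled exactly as a mouse symbol made up 0.05398% of rows (16 rows), against 47.91% (14202 rows) ignoring case, because human and mouse symbols of a gene often differ only in their capitals. No alternative setting of the treatment comparison was run. No paired analysis was possible because the value columns could not be assigned to the labelled samples.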
